A study of Mus musculus with 6 samples.

How the data were processed

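RNA of primary hepatic stellate cells from C57BL/6 mice was hybridised to 6 arrays, 3 for day 0 and 3 for day 7. Groups and replicate numbers were taken from the sample titles. Per the labels, the culture protocol of all 6 samples gives 7 days, which the titles of the day 0 samples contradict, and the titles were followed. Per the labels, total RNA was extracted with Trizol and RNeasy columns, amplified with a MessageAmp Premier kit and labelled with biotin. Per the submitters' processing notes, the authors computed the deposited log2 values with RMA in Affymetrix Expression Console 1.1, and the range of the values is that of log2 RMA values. RMA corrects the background, equalises the distribution of probe intensities between arrays and summarises the probes of a probe set. The probe set definition file and the settings of that step are not given in the sources used here. Equalising the distributions ties the arrays to a common scale, so a shift shared by most genes cannot be read from these values. No detection calls were in the table, and the array medians lay between 6.47 and 6.59.

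Probe sets were named through the platform annotation that accompanied the table. Of 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none. Of those with 1 symbol, 34741 were matched by gene identifier to a RefSeq gene table of the mouse genome, used for names only, and 0 symbols needed an update. Only probe sets with 1 symbol were tested. For each of 18193 genes, the probe set with the highest mean over all 6 arrays was used, which concerns the 9010 genes with more than 1 probe set. Among these, 1570 had probe sets that passed the threshold in opposite directions, 7 of them among the genes named by rule (Shh, Pck1, Ndufs4, Hyou1, Vps29, Snrpd3 and Rps9) and 11 among the other genes of the text. The 10092 probe sets without a single symbol were left out, and 1850 of them differed at least 2-fold between the days. No coordinates are given, because the build behind the values is not given in the sources used here.

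Days were compared with limma 3.58.1 in R 4.3.3, by a linear model per gene with the day as the only term and moderated variances, 2-sided, on the deposited log2 values of all 6 arrays. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05, and a further count required a fold of 2. Each adjusted p of a single gene in the text comes from this fit unless an alternative is named. A difference is the mean log2 value at day 7 minus that at day 0, with the standard error (SE) of the moderated fit.

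The comparison used 37 gene lists with 785 entries written from general knowledge, of which 724 matched a tested gene. The other entries were not analysed here. Each list was given as the number of members past the threshold, over all genes tested and adjusted over the list alone, and as its median. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01 between genes and, separately, with the correlation estimated from the arrays, with Benjamini-Hochberg over the 37 lists. At the preset correlation 21 lists passed, and 3 of them passed with the estimated one: quiescent stellate cell markers, hepatocyte markers and interferon-stimulated genes. The fry test, which asks whether the genes of a list move on balance one way without comparing them with other genes, passed for 35 lists. With a variance trend and robust fitting, camera was run on the moderated statistics of that fit (cameraPR), since camera itself has no robust option.

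Named genes followed a rule. Named were the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold with groups that did not overlap, 27 genes fixed by name, and up to 4 members of each list with the largest difference among those past the threshold (had none passed, 2 members would have been given as values). This gave 165 genes. The 27 were Shh, Ihh, Ptch1, Smo, Gli1, Gli2, Gli3, Hhip, Acta2, Col1a1, Pparg, Lrat, Hk2, Pkm, Ldha, Slc16a3, Hif1a, Pck1, Fbp1, Fasn, Srebf1, Cpt1a, Tgfb1, Mki67, Alb, Adgre1 and Pecam1. Lists of neuron, astrocyte, oligodendrocyte and Schwann cell markers were written later, after neuronal genes had been seen in day 0 replicate 1, and leave out the top genes seen there.

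The steps were tested on simulated data with the real number of genes (18193) and of arrays. With 50 genes at each size, the fit recovered 24% of changes of 0.25 log2 units, 68% at 0.5, 86% at 1 and 100% at 2. Of 147 calls 8 were false, and 2 of 100 random lists had a camera p under 0.05. The simulation changed few genes, whereas 13338 passed in the real data, so the cutoff differed and these shares do not carry over. Its noise was independent between genes, so the random lists do not test camera on correlated genes.

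The alternatives were the mean of a gene's probe sets, every named probe set by itself, a filter on dim genes, cyclic loess between arrays, centring on 13 housekeeping genes, variances with a trend and robust fitting, array weights, the replicate number as a block, an unmoderated statistic, an adjusted p under 0.01, a test against a fold of 1.5, and leaving out each array in turn. A planned comparison of RNA quality between 3' and 5' control probe sets could not be made, because the table held 0 such control probe sets.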

Results

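RNA levels were measured on 6 Affymetrix mouse expression arrays, each hybridised with RNA of primary hepatic stellate cells from C57BL/6 mice. Hepatic stellate cells lie along the liver sinusoid and store vitamin A, and they turn into contractile, matrix-producing myofibroblasts in culture and in injured liver. The arrays formed 2 groups of 3, day 0 cells in an early state and day 7 cells in the myofibroblastic state. The series title names hedgehog signalling and metabolism, so that the question was which genes of these and related pathways differed between both states. Each array gave a log2 RMA value for 45037 probe sets, and 18193 genes were tested with 1 probe set each. The values had a median of 6.53 and a 25th percentile of 5.04. The table carried no detection calls, so folds that start or end below that percentile are compressed. The small number of arrays limits the precision. The days come from the sample titles, while the culture protocol in the labels gives 7 days for all 6 samples, so what day 0 stands for rests on the titles and on descriptions of early cells. The labels call the samples biological replicates without naming separate isolations or animals, so the p-values measure only the spread between these samples, which may be technical. Groups, the tests of the comparison, its 37 gene lists and the rule for named genes were set before the data were examined, while the neural marker lists and most tests of explanations were set later. Genes named beside that rule, such as members that went against their list, were chosen after their values were seen. For 18 genes in the text, probe sets passed in opposite directions, so that their direction is not settled: Shh, Pck1, Ndufs4, Hyou1, Vps29, Snrpd3, Rps9, Cox7c, Dhh, Dlc1, Egr3, Epcam, Mbp, Mcm7, Nes, Pfkp, Shmt1 and Uqcrb.

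Arrays of the same day correlated across genes at r = 0.995 to 0.998, and arrays of different days at r = 0.875 to 0.878, where genes are not independent replicates. The first principal component carried 96.5% of the variance and separated the days. No arrays held identical values, with 0 such pairs. Day 0 replicate 1 stood apart from the other day 0 arrays by neuronal transcripts. Snap25, a synaptic vesicle fusion protein, read 10.1 there against 2.90 and 3.09 in the other day 0 arrays. Nrgn, a postsynaptic calmodulin-binding protein, read 10.8 against 6.35 and 6.64. In that array 95 genes lay over 1 log2 unit above both other arrays of the day, against 0 or 1 in each of the other 5 arrays. Without it, 4014 genes changed at least 2-fold, of which 3892 were shared with the 3965 found with all arrays. Of the genes named below, Cd4, Cdon, Ebp and Ltf lost their calls without it.

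At day 7, the lists of contractile and matrix-modifying genes were higher, and those of quiescent stellate, sinusoidal endothelial and hepatocyte markers were lower. The stellate and hepatocyte lists also passed with the correlation between genes estimated (adjusted p = 0.028 each with an estimated correlation), unlike the contractile (adjusted p = 0.121), matrix (adjusted p = 0.254) and endothelial lists (adjusted p = 0.0655). Acta2, the smooth muscle actin of myofibroblasts, was 6.33-fold higher at day 7 (log2 difference 2.66 ± 0.05 SE, n = 3 per day, limma adjusted p = 1.41e-08). Its day 7 values (14.94 to 14.95) were the highest of each day 7 array, at the top of the scale, so this fold is not exact, and its other probe sets gave 4.72 and 1.98. Lrat, which esterifies retinol for storage, showed the largest fall of all genes, a log2 difference of -9.43 ± 0.11 SE (adjusted p = 4.43e-09), from a mean of 13.51 at day 0 to 4.08. The other large falls were those of Serpina1b (-8.94), a secreted protease inhibitor of hepatocytes, the hepatocyte cytochrome Cyp3a11 (-8.81), the sinusoidal endothelial lectin Clec4g (-8.80), the DNase Dnase1l3 (-8.52) and the stellate cell glycoprotein Reln (-8.35). The largest rises were those of the hyaluronan-binding protein Cemip (8.86 ± 0.12 SE, adjusted p = 4.76e-09), the calcium-binding protein S100a4 (7.92), the heparan sulfate sulfotransferase Hs6st2 (7.37), the cytokine Il6 (7.02), the acute phase protein Saa3 (6.80) and sciellin, Scel (6.75). In each named gene past the threshold, all 3 day 7 arrays lay on the same side of all 3 day 0 arrays.

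Of the 18193 genes, 13338 (73.3%) differed between the days at an adjusted p under 0.05 in limma, 8344 of them higher and 4994 lower at day 7. A change of at least 2-fold was seen in 3965 genes, 1902 higher and 2063 lower. Changes of at least 8-fold were more often falls, with 493 genes lower and 188 higher. The groups did not overlap in 13897 genes (76.4%), where chance gives 10%. The split by direction followed the scaling: cyclic loess gave 6255 higher and 6165 lower, and centring on 13 housekeeping genes gave 3526 higher and 9698 lower. The median log2 difference of all genes was 0.17 as deposited, 0.04 after cyclic loess and -0.26 after centring on the housekeeping genes, and that centring lowers each difference by 0.43, so that smaller rises turn under it and some differences near 0 pass as lower.

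**Figure D1:**
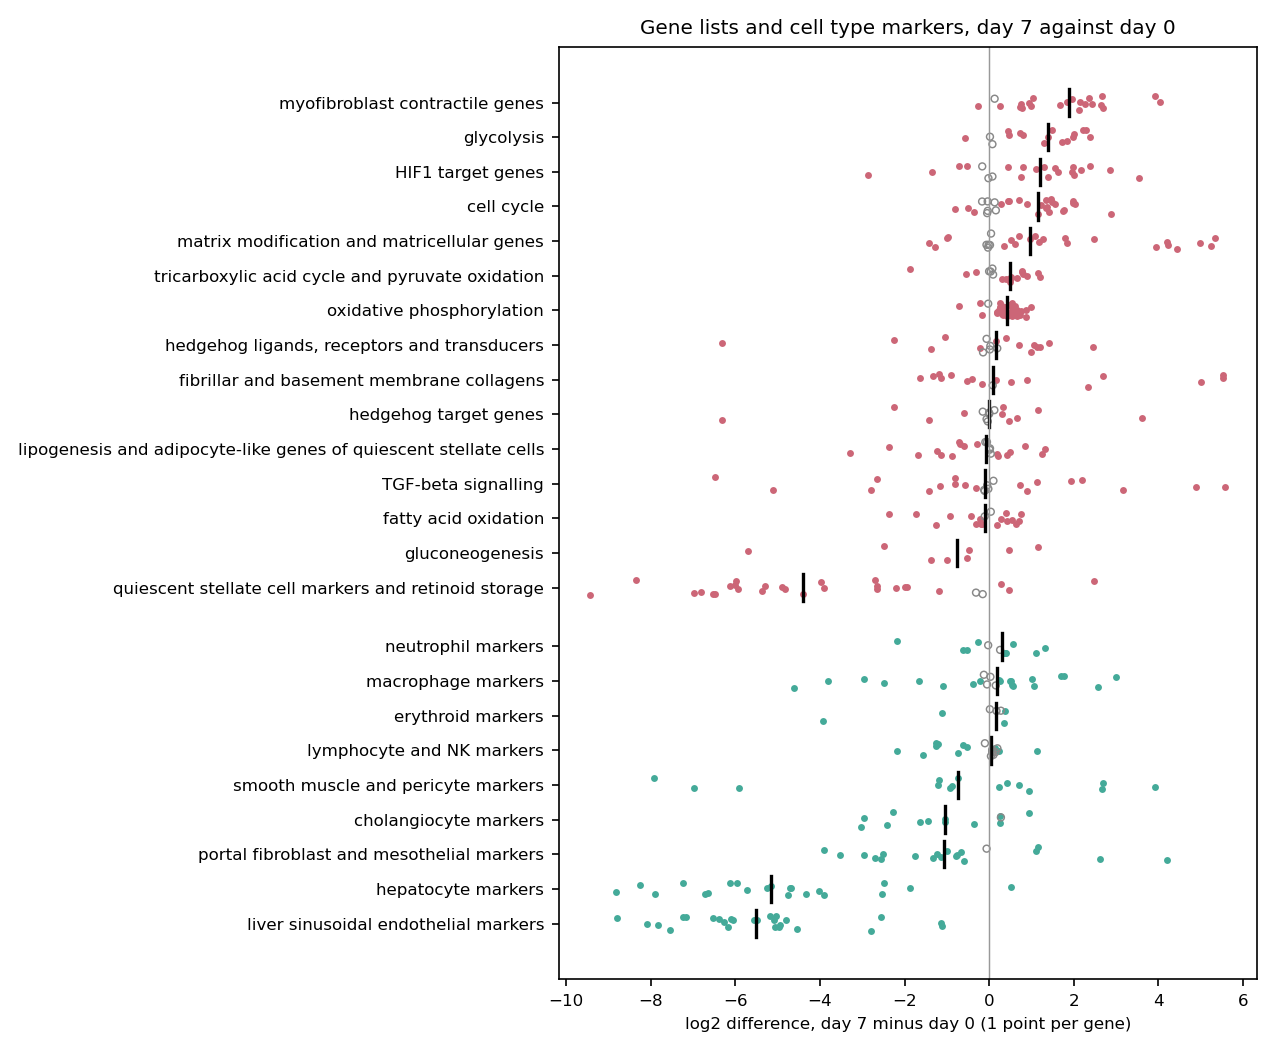
Log2 difference between day 7 and day 0 (horizontal axis, 1 point per gene) for the members of 24 gene lists, with pathway lists in red and markers of other cell types in green. Filled points passed an adjusted p of 0.05, open points did not, and the black bar is the median, which reached 1.90 for contractile genes and -5.52 for sinusoidal endothelial markers.

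Contractile genes of myofibroblasts were higher at day 7. Of 22 measured, 20 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 difference of 1.90. The list passed limma's camera test against all other genes (adjusted p = 1.67e-06), though not with the correlation between genes estimated (adjusted p = 0.121 with an estimated correlation). The smooth muscle actin Actg2 rose by 4.03, the actin-binding calponin Cnn1 by 3.92 and the leiomodin Lmod1 by 2.70. Non-muscle myosin Myh9 was the member that fell (-0.26 in the probe set used). Another of its probe sets fell (-0.50), and the others did not pass (-0.06, 0.04 and 0.09). The light chain kinase Mylk did not pass in the probe set used (0.13), while its other probe sets rose (0.44 and 0.39). As endothelial and hepatocyte markers fell, a rising share of stellate cells cannot be told apart from a change within them for this list. The same holds for the other lists that rose, and it was not tested.

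Matrix-modifying and matricellular genes also rose as a list, with 18 of 27 higher and 4 lower (18 and 4 adjusted over the list alone) and a median of 0.97 (camera adjusted p = 0.00724, adjusted p = 0.254 with an estimated correlation). Lysyl oxidase, Lox, which cross-links collagen, rose by 5.33, the metalloproteinase inhibitor Timp1 by 5.25, and the matrix metalloproteinases Mmp13 by 4.99 and Mmp3 by 4.43. The members that fell were the small proteoglycans Lum (-1.41) and Dcn (-0.98), periostin, Postn (-1.27), and elastin, Eln (-0.999). Collagens went both ways: 8 of 17 rose and 8 fell (8 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.931, adjusted p = 0.958 with an estimated correlation). Their median was 0.08 and their mean 0.91 while camera pointed down (up with a variance trend and robust fitting or housekeeping centring), and the median was -0.24 after cyclic loess and -0.35 after housekeeping centring. Col1a1, a chain of the main fibrillar collagen of scars, rose by 2.70 ± 0.05 SE (6.51-fold, adjusted p = 2.10e-08), and Col11a1 (5.54), Col12a1 (5.53) and Col8a1 (5.01) rose further. The type VI chains Col6a1 (-0.90), Col6a2 (-1.18) and Col6a3 (-1.64) fell.

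Markers of quiescent stellate cells and of retinoid storage fell. Of 29 measured, 24 fell and 3 rose (24 and 3 adjusted over the list alone), with a median of -4.40, and the list passed camera with the preset correlation and with the estimated one (adjusted p = 1.05e-12, and adjusted p = 0.028 with an estimated correlation). Beside Lrat and Reln, the largest falls were those of the G protein regulator Rgs5 (-6.98) and the vasoactive intestinal peptide receptor Vipr1 (-6.80). The 3 that rose were Aldh1a2 (2.47), which makes retinoic acid, the retinol transporter Stra6 (0.46) and the intermediate filament Nes (0.28). Gfap (-0.15) and Bmp10 (-0.31) did not pass. The Gfap probe set used read 7.46 in day 0 replicate 1 against 6.49 and 6.47, and its difference was 0.17 without that array, while its other probe sets fell (-0.67 and -0.82). Bmp10 passed without that array (-0.44, adjusted p = 0.0338).

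Markers of other liver cells moved in the same comparison. All 26 measured sinusoidal endothelial markers fell (26 adjusted over the list alone), with a median of -5.52 (camera adjusted p = 1.49e-16, adjusted p = 0.0655 with an estimated correlation). Among them were the hyaluronan receptor Lyve1 (-8.09), the scavenger receptor Stab2 (-7.82), the orphan receptor Gpr182 (-7.55) and the junction protein Pecam1 (-5.05 ± 0.22 SE). Of 21 hepatocyte markers 20 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -5.15 (camera adjusted p = 8.97e-13, adjusted p = 0.028 with an estimated correlation). Albumin, Alb, fell from a mean of 13.86 to 5.96 (-7.89 ± 0.16 SE), and the fibrinogen chains Fga (-8.27) and Fgg (-7.25) fell. The member that rose, Ass1 (0.52), makes argininosuccinate. Its means of 5.36 at day 0 and 5.88 at day 7 lay below the table median of 6.53, so this rise is weak evidence of an exception.

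Cholangiocyte markers fell as a list, 9 of 13 lower and 3 higher (9 and 3 adjusted over the list alone), with a median of -1.05 (camera adjusted p = 0.00556, adjusted p = 0.144 with an estimated correlation). Among them were the epithelial keratins Krt8 (-3.03), Krt19 (-2.97) and Krt18 (-2.41) and the claudin Cldn7 (-2.27), while the anion exchanger Slc4a2 (0.95), Epcam (0.26, another probe set -2.55) and Sox9 (0.26) rose. Portal fibroblast and mesothelial markers fell too, 15 of 20 lower and 4 higher (15 and 4 adjusted over the list alone), with a median of -1.06 (camera adjusted p = 6.87e-04, adjusted p = 0.205 with an estimated correlation), and did not pass after housekeeping centring (0.0970). Dermatopontin, Dpt (-3.91), and Pi16 (-3.52) fell, while the matrix protein Fbln2 (4.21), Thy1 (2.63), Upk1b (1.16) and Wt1 (1.11) rose.

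Smooth muscle and pericyte markers split, 7 of 15 higher and 8 lower (7 and 8 adjusted over the list alone; camera adjusted p = 0.294, adjusted p = 0.519 with an estimated correlation), with 4 higher and 9 lower after housekeeping centring. The subunits of a vascular potassium channel, Abcc9 (-7.92) and Kcnj8 (-5.90), fell, and the contractile genes Cnn1 and Lmod1 rose. Macrophage markers split as well, 12 of 24 higher and 8 lower (13 and 8 adjusted over the list alone; camera adjusted p = 0.931, adjusted p = 0.958 with an estimated correlation). After cyclic loess 10 rose and 10 fell, and after housekeeping centring 6 rose and 14 fell. The median of that list was 0.20 as deposited, -0.03 after cyclic loess and -0.24 after housekeeping centring, and its mean was -0.14. The macrophage surface receptor Adgre1 rose by 1.02 ± 0.08 SE and the integrin Itgam by 3.00. Cd163 (-4.62), Clec4f (-3.81) and Timd4 (-2.96), known from liver-resident macrophages, fell.

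Lymphocyte and natural killer cell markers did not pass as a list. Of 19 measured, 3 rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.129, adjusted p = 0.519 with an estimated correlation). Their median was 0.04 and their mean -0.38, and the median turned negative with cyclic loess (-0.11) and housekeeping centring (-0.39), where 1 rose and 17 fell. The T cell receptor chain Cd3g (-2.17), the chemokine Ccl5 (-1.56) and the killer cell genes Klrd1 (-1.26) and Nkg7 (-1.26) fell, and the receptor Il7r (1.14), Cd8a (0.23) and Cd4 (0.15) rose. Neutrophil markers gave 6 of 12 higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.958, adjusted p = 0.958 with an estimated correlation), with a median of 0.30 that was -0.13 after housekeeping centring, where 2 rose and 5 fell. The calcium-binding proteins S100a9 (-2.17) and S100a8 (-0.52), the granulocyte colony-stimulating factor receptor Csf3r (-0.61) and lactoferrin, Ltf (-0.27), fell, while Mmp8 (1.32) and Camp (1.10) rose. Erythroid markers gave 2 of 7 higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.661, adjusted p = 0.703 with an estimated correlation), with a median of 0.17, -0.26 after housekeeping centring, and a mean of -0.55. The transcription factor Tal1 (-3.93) and the haem synthesis enzyme Alas2 (-1.10) fell. The alpha globin gene Hba-a1 (0.37) and Klf1 (0.36) rose at low levels, and both were -0.07 after housekeeping centring. Klf1 lost its call after cyclic loess (0.24, adjusted p = 0.101), with the replicate block (adjusted p = 0.0608) and without day 0 replicate 2 (0.29) or day 7 replicate 2 (0.25).

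Within the hedgehog pathway, Hhip and Ptch1 fell and several transducers rose, while the list as a whole did not pass. Hhip, which binds and sequesters hedgehog ligands, fell 79.4-fold (-6.31 ± 0.09 SE, adjusted p = 4.76e-09), from a mean of 10.65 to 4.34, and each of its 4 probe sets fell, with differences from -6.31 to -3.67. Ptch1, the ligand receptor that holds the pathway off and is itself induced by it, fell 4.73-fold (-2.24 ± 0.08 SE, adjusted p = 2.56e-07). Of its 3 probe sets, 2 fell (-2.24 and -0.85), and the remaining one did not pass (0.05). The signal transducer Smo rose by 1.13 ± 0.08 SE (2.19-fold, adjusted p = 1.02e-05), and the transcription factors Gli2 and Gli3 rose by 1.06 ± 0.13 SE and 0.71 ± 0.05 SE. Disp1, which releases ligands from producing cells, rose by 2.45 and the co-receptor Boc by 1.42. Gli1, the transcription factor most directly induced by the pathway, differed by less than the spread between arrays (-0.06 ± 0.13 SE, adjusted p = 0.690). Its means of 6.22 and 6.16 lay below the median of the table, and without day 7 replicate 1 its difference was 0.07. After housekeeping centring Gli1 passed as lower (-0.49, adjusted p = 0.00945).

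Among the ligands, Shh fell by 1.37 ± 0.20 SE in the probe set used (adjusted p = 5.95e-04) and rose by 0.45 in the other, so that its direction is not settled. Dhh fell by 1.05 in the probe set used and rose by 0.27 in the other, and the co-receptor Cdon fell by 0.22. Ihh did not pass (0.03 ± 0.10 SE, adjusted p = 0.802), and its difference was -0.10 after cyclic loess. After housekeeping centring it passed as lower (-0.40, adjusted p = 0.00947), and it was also negative without day 7 replicate 1 (-0.01) or day 7 replicate 3 (-0.04).

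As a list, 9 of the 19 measured hedgehog ligands, receptors and transducers rose and 5 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.878, adjusted p = 0.875 with an estimated correlation). The median was 0.16 and the mean -0.09, and after housekeeping centring the median was -0.28, with 7 higher and 10 lower. Of 16 hedgehog target genes, 6 rose and 4 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.661, adjusted p = 0.703 with an estimated correlation). Their median of 0.00 became -0.12 after cyclic loess and -0.43 after housekeeping centring, where 3 rose and 10 fell, and their mean was -0.26. Beyond Hhip and Ptch1, which both lists hold, the Wnt antagonist Sfrp1 rose by 3.61 and the mesenchymal transcription factor Foxf1 (-1.41) and the survival gene Bcl2 (-0.58) fell. The endothelial and hepatocyte marker lists had medians of -5.52 and -5.15 in the same comparison.

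**Figure D2:**
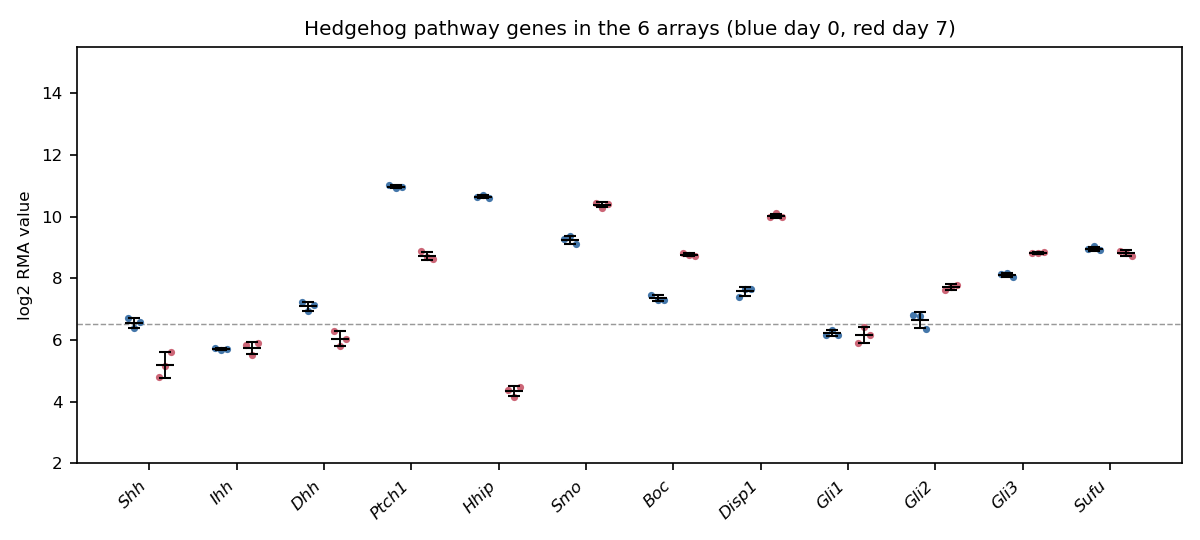
Log2 RMA values (vertical axis) of 12 hedgehog pathway genes in the 3 day 0 arrays (blue) and the 3 day 7 arrays (red), with bars for mean and SD and a dashed line at the table median of 6.53. Hhip went from a mean of 10.65 to 4.34 and Smo from 9.25 to 10.38, while the Gli1 groups overlapped.

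Genes of glycolysis were higher at day 7. Of 17 measured, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 1.40 (camera adjusted p = 0.00163, adjusted p = 0.329 with an estimated correlation). Hexokinase 2, Hk2, which commits glucose to the pathway, rose 5.25-fold (2.39 ± 0.10 SE, adjusted p = 5.57e-07). Pgam1 rose by 2.30, Eno2 by 2.23 and the lactate exporter Slc16a3 by 2.02 ± 0.15 SE. The pyruvate kinase gene Pkm rose 2.63-fold (1.40 ± 0.10 SE, adjusted p = 1.36e-05) and lactate dehydrogenase A, Ldha, 2.46-fold (1.30 ± 0.06 SE, adjusted p = 1.18e-06). Pfkp, a phosphofructokinase isoform, was the member that fell (-0.56, another probe set 1.00). The hexokinase Hk1 (0.02) and the regulator Pfkfb3 (0.08) did not pass in the probe sets used, while another probe set of each rose (0.60 and 0.26).

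Target genes of the hypoxia-inducible factor HIF1 rose as a list, 15 of 22 higher and 4 lower (15 and 4 adjusted over the list alone), with a median of 1.20 (camera adjusted p = 0.0329, adjusted p = 0.345 with an estimated correlation). It did not pass with the filter on dim genes (0.0636) or with the replicate block (0.0592). Hif1a itself rose 3.90-fold (1.96 ± 0.05 SE, adjusted p = 5.44e-08). The collagen lysyl hydroxylase Plod2 rose by 3.55 and the angiogenic factor Vegfa by 2.86, while the stress-response gene Ndrg1 (-2.85), the carbonic anhydrase Car9 (-1.35), Kdm3a (-0.71) and Ddit4 (-0.53) fell. The list holds several glycolysis genes, among them Hk2, Ldha and Slc16a3.

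Gluconeogenesis genes fell as a list, 6 of 8 lower and 2 higher (6 and 2 adjusted over the list alone), with a median of -0.76 (camera adjusted p = 0.0347, adjusted p = 0.205 with an estimated correlation). That call was also lost with the filter on dim genes (adjusted p = 0.564), after cyclic loess (adjusted p = 0.0947) and after housekeeping centring (adjusted p = 0.221). Fructose bisphosphatase 1, Fbp1, fell 52.2-fold (-5.71 ± 0.10 SE, adjusted p = 1.32e-08). The glucose 6-phosphatase gene G6pc (-2.48) and the transcriptional coactivator Ppargc1a (-1.37) fell as well. Pck1, the cytosolic phosphoenolpyruvate carboxykinase, fell by 0.48 ± 0.12 SE in the probe set used, whereas its other probe sets gave -4.34 and 0.39. The mitochondrial isoform Pck2 rose by 1.16 and pyruvate carboxylase, Pcx, by 0.46. The gene G6pc is also on the hepatocyte marker list, which had a median of -5.15 in the same comparison.

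Among mitochondrial genes, 29 of 33 members of the oxidative phosphorylation list rose and 3 fell (29 and 3 adjusted over the list alone), with a median of 0.42 as deposited, 0.11 after cyclic loess and -0.01 after housekeeping centring. The list passed as deposited (camera adjusted p = 0.00285) but not after cyclic loess (0.121), after centring (0.0890) or with the correlation estimated (adjusted p = 0.379 with an estimated correlation). After centring, 9 rose and 11 fell. The ATP synthase subunits Atp5o (0.98) and Atp5pb (0.87), the complex I subunit Ndufs4 (0.88) and the cytochrome oxidase subunit Cox5a (0.76) rose most, although the probe sets of Ndufs4 went both ways and their mean gave -0.08. The members that fell were Cox7c (-0.72), Ndufv1 (-0.22) and Uqcrb (-0.17). In the tricarboxylic acid cycle and pyruvate oxidation list, 14 of 21 rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 0.50. After cyclic loess 13 rose and 7 fell (median 0.25), and after housekeeping centring 7 rose and 7 fell (median 0.06). The list did not pass (camera adjusted p = 0.0616, adjusted p = 0.519 with an estimated correlation), although it passed as higher with a variance trend and robust fitting (0.0268). Idh3a rose by 1.20, and the pyruvate dehydrogenase components Dlat and Pdha1 rose by 1.16 and 0.91. Pdk4 (-1.87), a kinase that inactivates that complex, fell, as did Ogdh (-0.54) and Idh3g (-0.31).

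**Figure D3:**
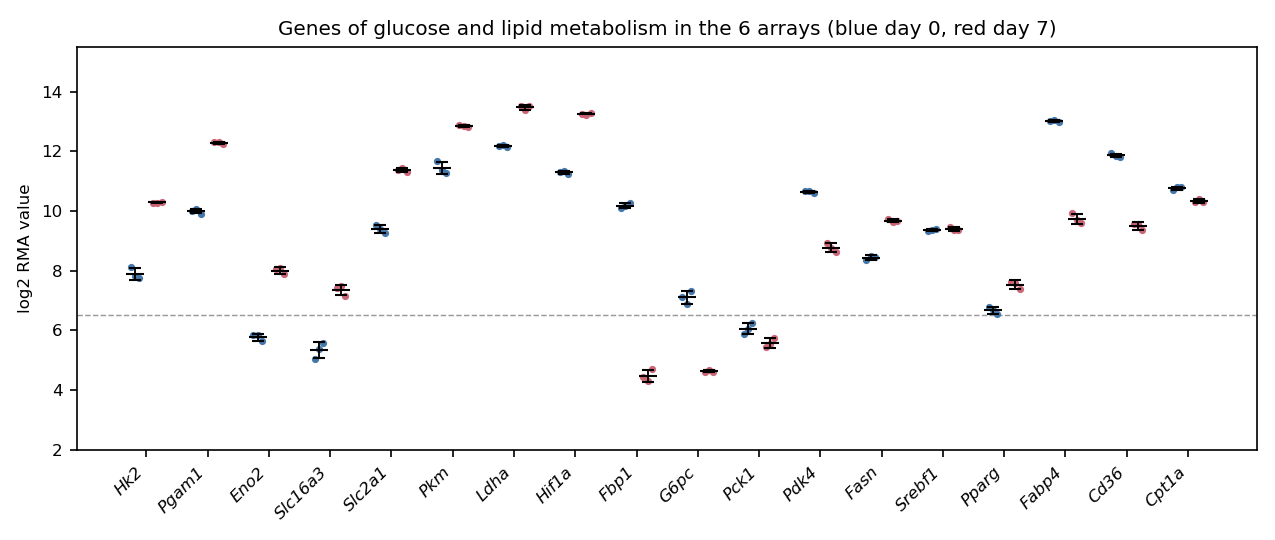
Log2 RMA values (vertical axis) of 18 genes of glucose and lipid metabolism in the 3 day 0 arrays (blue) and the 3 day 7 arrays (red), with bars for mean and SD and a dashed line at the table median of 6.53. Hk2 went from a mean of 7.89 to 10.29 and Fbp1 from 10.19 to 4.48, while Srebf1 stayed at 9.37 and 9.39.

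Lipid genes were divided. In the list of lipogenesis and adipocyte-like genes, 7 of 22 rose and 10 fell (7 and 10 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0641, adjusted p = 0.519 with an estimated correlation). After housekeeping centring 3 rose and 17 fell. The list passed as lower after cyclic loess (0.0244, with 4 higher and 15 lower) and without day 7 replicate 1 (0.0444). The fatty acid carrier Fabp4 (-3.28), the fatty acid transporter Cd36 (-2.36) and the glucose-responsive transcription factor Mlxipl (-1.68) fell. Fatty acid synthase, Fasn, rose by 1.24 ± 0.06 SE (2.36-fold, adjusted p = 1.55e-06), the desaturase Scd2 by 1.33, and Pparg, the adipogenic nuclear receptor, by 0.86 ± 0.09 SE (1.81-fold, adjusted p = 9.86e-05). Srebf1, a transcriptional regulator of lipogenesis, did not pass (0.02 ± 0.05 SE, adjusted p = 0.741), but passed as lower after cyclic loess (-0.16, adjusted p = 0.0277) and housekeeping centring (-0.41, adjusted p = 4.43e-04). Without day 7 replicate 1 its difference was -0.01. Of 19 genes of fatty acid oxidation, 8 rose and 9 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.377, adjusted p = 0.731 with an estimated correlation). These counts were 6 and 11 after cyclic loess and 3 and 13 after housekeeping centring, with medians of -0.10 as deposited, -0.31 and -0.54. The beta-oxidation enzymes Acaa2 (-2.37), Ehhadh (-1.72) and Hadh (-0.92) fell, as did the nuclear receptor Ppara (-1.26). The other probe sets of Hadh did not pass (-0.06 and -0.008). In the same comparison the endothelial and hepatocyte marker lists had medians of -5.52 and -5.15. Cpt1a, which admits fatty acids to mitochondria, fell by 0.43 ± 0.06 SE in the probe set used (adjusted p = 3.31e-04), while its other probe sets and the mean of all (-0.10) did not pass.

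Cell cycle genes rose as a list, 20 of 29 higher and 3 lower (20 and 3 adjusted over the list alone), with a median of 1.15 (camera adjusted p = 0.00940, adjusted p = 0.379 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 rose by 2.87, and the mitotic genes Bub1, Tpx2 and Birc5 rose by 2.02, 1.99 and 1.97. Mki67, a marker of proliferating cells, rose by 0.46 ± 0.09 SE (adjusted p = 0.00247) as deposited but by 0.02 after housekeeping centring, where it did not pass. The members that fell were Cenpa (-0.49), a centromeric histone, and the replication licensing genes Mcm3 (-0.80) and Mcm7 (-0.37).

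In the TGF-beta list, 8 of 23 genes rose and 10 fell (8 and 10 adjusted over the list alone; camera adjusted p = 0.212, adjusted p = 0.676 with an estimated correlation). After housekeeping centring 8 rose and 15 fell. The activin antagonist Fst rose by 5.58 and the latent TGF-beta binding protein Ltbp2 by 4.88. Its relative Ltbp4 (-5.10) and the TGF-beta-induced protein Tgfbi (-6.48) fell. Tgfb1 itself fell 2.24-fold (-1.16 ± 0.05 SE, adjusted p = 7.30e-07). Target genes of the mechanosensitive cofactor YAP rose, 16 of 20 higher and 2 lower (16 and 2 adjusted over the list alone), with a median of 1.17 (camera adjusted p = 0.00163, adjusted p = 0.205 with an estimated correlation). Tissue factor, F3, rose by 5.74, Ankrd1 by 5.58, Foxf2 by 3.21 and the receptor kinase Axl by 1.90, while Dlc1 (-1.55) and Nuak2 (-0.92) fell.

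Among other signalling genes, 9 of 26 Wnt pathway members rose and 11 fell (9 and 11 adjusted over the list alone; camera adjusted p = 0.449, adjusted p = 0.519 with an estimated correlation), with a median of -0.03 and a mean of 0.14. After housekeeping centring 9 rose and 15 fell. Dkk2 rose by 3.48 and the receptor Fzd2 by 3.29, whereas the ligand Wnt2 fell by 5.04. Notch genes fell as a list, 12 of 19 lower and 6 higher (12 and 6 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 0.0110, adjusted p = 0.164 with an estimated correlation); after housekeeping centring the list did not pass (0.0852). The receptors Notch4 (-5.57) and Notch1 (-4.07), the feedback regulator Nrarp (-3.83) and the ligand Dll4 (-3.51) fell, and all are known from endothelial cells, whose markers had a median of -5.52 in the same comparison. Of 21 genes of PDGF and other mitogen signalling, 13 rose and 7 fell (13 and 7 adjusted over the list alone; camera adjusted p = 0.661, adjusted p = 0.867 with an estimated correlation), with a median of 0.72 and a mean of -0.18. After housekeeping centring 11 rose and 10 fell. The growth factor Fgf2 rose by 3.82. The receptors Kdr (-6.11), which is also an endothelial marker, Ednrb (-4.63) and Agtr1a (-4.17) fell.

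Immediate early genes, which tissue dissociation is known to induce, were lower at day 7, 20 of 22 lower and 1 higher (20 and 1 adjusted over the list alone), with a median of -2.12 (camera adjusted p = 1.84e-10, adjusted p = 0.0655 with an estimated correlation). The transcription factors Fosb (-6.69), Fos (-4.75), Jun (-4.17) and Atf3 (-3.67) fell, and Egr3 (0.54, another probe set -1.69) was the member that rose. Endothelial and hepatocyte markers, with medians of -5.52 and -5.15, fell in the same comparison. Inflammatory cytokines and chemokines went both ways, with 10 of 22 higher and 12 lower (10 and 12 adjusted over the list alone; camera adjusted p = 0.449, adjusted p = 0.682 with an estimated correlation), a median of -0.21 and a mean of 0.50. Beside Il6, the chemokines Cxcl5 and Ccl7 rose by 5.44 and 4.84 and the prostaglandin synthase Ptgs2 rose by 4.93, while the interleukins Il1a (-4.03) and Il1b (-1.84) fell.

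**Figure D4:**
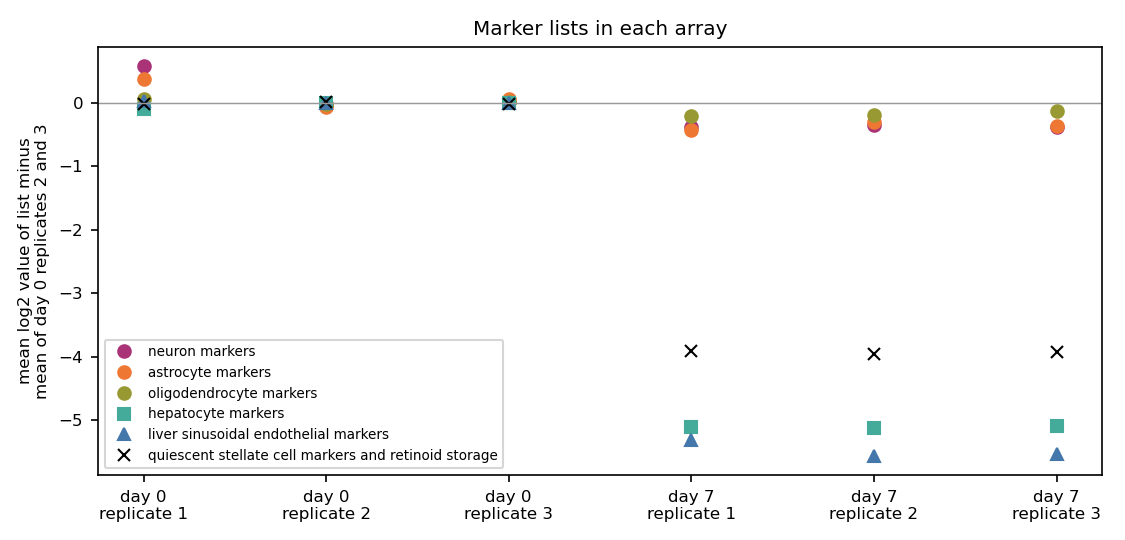
Mean log2 value of 6 marker lists in each array, minus the mean of day 0 replicates 2 and 3 (vertical axis, log2 units), with the brightest probe set of each gene. The neuron list lay 0.58 higher in day 0 replicate 1 than in the other day 0 arrays, and the hepatocyte, sinusoidal endothelial and quiescent stellate lists separated the days in all 6 arrays.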

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

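Each alternative was planned before the data were examined, and each was run. Of 93 recomputed counts 83 stayed within 1.5 times the reported one. Of 517 list tests 471, and of 2123 values of named genes 2105, kept their direction and their side of the threshold. Of the 165 named genes, 140 were list members picked for their large differences in this fit, so their stability was to be foreseen. The list tests include lists that never passed, and 18 lists lost their call with the estimated correlation. Centring on the housekeeping genes gave 3526 genes higher and 9698 lower, and 1002 and 3229 at 2-fold or more. Testing every named probe set gave 24633 changed (15530 higher, 9103 lower) and 7502 at 2-fold or more (3716 higher, 3786 lower), since more features were tested. Leaving out 1 array gave 12441 to 12996 changed genes and 3947 to 4014 at 2-fold or more.

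With the correlation between genes estimated, the adjusted p of lists that had passed became 0.329 for glycolysis, 0.205 for gluconeogenesis, 0.379 for oxidative phosphorylation, 0.345 for HIF1 targets, 0.121 for contractile genes, 0.254 for matrix modification and 0.379 for the cell cycle. The filter on dim genes gave 0.564 for gluconeogenesis and 0.0636 for HIF1 targets. Cyclic loess gave 0.0947 for gluconeogenesis, 0.121 for oxidative phosphorylation and 0.0244 for lipogenesis, which then passed. Housekeeping centring gave 0.221 for gluconeogenesis and 0.0890 for oxidative phosphorylation, and turned collagens upward (0.426). Variances with a trend and robust fitting gave 0.0268 for the tricarboxylic acid cycle, which then passed, and turned collagens upward (0.901). Leaving out 1 array gave 0.0444 to 0.0910 for lipogenesis, which passed without day 7 replicate 1.

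Lists that never passed also turned: with housekeeping centring, inflammation (0.537), Wnt (0.671), macrophage (0.680) and smooth muscle (0.999); with the filter, macrophage (0.848) and neutrophil (0.811); with the mean of probe sets, neutrophil (0.988); with a trend and robust fitting, macrophage (0.928). Leaving out 1 array gave 0.863 to 0.972 for neutrophil markers, which turned without day 7 replicate 1 or 3.

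Among named genes, cyclic loess turned Ihh (-0.10) and Srebf1 (-0.16), and housekeeping centring turned Ihh (-0.40), Srebf1 (-0.41), Hba-a1 (-0.067) and Klf1 (-0.071). The mean of probe sets turned Ndufs4 (-0.084), since these disagree. With 1 array left out, Ihh ranged from -0.043 to 0.14, Gli1 from -0.19 to 0.072 and Srebf1 from -0.014 to 0.043. Where no cause is given here, the cause was not tested.

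No pairing by replicate number was seen: same-numbered arrays deviated from their group means with correlations of 0.01, -0.00 and 0.08. That does not exclude a shared isolation, which the labels leave open. With a replicate block, 13190 genes changed and 3966 at 2-fold or more, and of the 37 lists and the 165 genes named by rule only HIF1 targets (0.0592) and Klf1 (0.36, adjusted p = 0.0608) lost their calls. With no detection calls, the signal over background limits what can be said of genes below 5.04, the 25th percentile of all values.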

Other observations

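Tests of explanations on stellate, endothelial, hepatocyte and portal markers and on Hhip and Ptch1 were chosen only after the results were seen, and the neural marker lists were written after neuronal genes had been seen but before the lists were tested. The single probe sets of Mbp were examined after that, and how the tests on portal markers, Ptch1, brain and nerve were read was revised after their values were known. Interferon-stimulated genes were lower at day 7, 18 of 19 lower and 1 higher (18 and 1 adjusted over the list alone), with a median of -1.52 (camera adjusted p = 1.11e-09, adjusted p = 0.028 with an estimated correlation). The antiviral genes Rsad2 (-4.30), Oas1a (-3.49) and Oasl2 (-2.77) and the transcription factor Irf1 (-2.89) fell. Ifit1 (0.20) was the member that rose, as deposited only: after cyclic loess 0 rose, and after housekeeping centring 19 fell. Endothelial and hepatocyte markers fell in the same comparison, with medians of -5.52 and -5.15. Genes of cholesterol synthesis were higher, 15 of 17 higher and 1 lower (15 and 1 adjusted over the list alone), with a median of 1.39 (camera adjusted p = 6.07e-04, adjusted p = 0.223 with an estimated correlation). Squalene epoxidase, Sqle, rose by 3.52, Cyp51 by 3.27, Fdps by 2.42 and Msmo1 by 2.37, and Ebp fell by 0.17. Genes of glutamine and serine metabolism rose as a list, 12 of 16 higher and 3 lower (12 and 3 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 0.0384, adjusted p = 0.254 with an estimated correlation), and did not pass with the filter on dim genes (0.0636). The serine synthesis genes Psat1 and Phgdh rose by 4.63 and 3.26, asparagine synthetase, Asns, by 4.61 and the mitochondrial folate enzyme Mthfd2 by 2.78. Glutamine synthetase, Glul (-2.49), Slc3a2 (-0.60) and Shmt1 (-0.29) fell.

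The pentose phosphate and glutathione list rose, 11 of 14 higher and 2 lower (11 and 2 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 0.0199, adjusted p = 0.223 with an estimated correlation). Haem oxygenase 1, Hmox1, rose by 2.75, glutathione synthetase, Gss, by 1.32, Nqo1 by 1.30 and the thioredoxin reductase Txnrd1 by 1.19, while Rpia (-0.99) and Gclc (-0.37) fell. The largest rises lie outside the pentose phosphate pathway, so the call of the list is not one for that pathway by itself. The unfolded protein response list fell, 13 of 20 lower and 4 higher (13 and 4 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.00304, adjusted p = 0.121 with an estimated correlation). Atf3 (-3.67), which is also an immediate early gene, and the chaperone Hyou1 (-1.08, with probe sets that disagreed) fell, while Ddit3 (1.51), Trib3 (1.08), Edem1 (0.47) and Atf4 (0.22) rose. Cytosolic ribosomal proteins gave 13 of 14 higher and 0 lower (14 and 0 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.00387, adjusted p = 0.205 with an estimated correlation). That call was lost after cyclic loess (0.253), with 7 higher and 3 lower, and housekeeping centring (0.0890), with 5 and 3. Rpl37 rose by 1.11, Rps6 by 0.77, Rplp0 by 0.76 and Rps9 by 0.73. Of the 13 housekeeping genes used for centring, 10 rose and 0 fell as deposited (10 and 0 adjusted over the list alone; camera adjusted p = 0.0543, adjusted p = 0.223 with an estimated correlation), with a median of 0.42 that was -0.02 after the centring itself. The list passed with a variance trend and robust fitting (0.0176). Reep5 rose by 1.03, Psmb2 by 0.83, Vps29 by 0.81 and Snrpd3 by 0.66, as deposited, in the probe sets used. The other probe sets of Reep5 did not pass (0.14 and 0.25), and those of Vps29 and Snrpd3 went both ways. The centring thus depends in part on the probe sets used.

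The 3 against 3 design gives 10 splits of the arrays, too few for a share under 0.05. The real split gave 13338 changed genes and 3965 at 2-fold or more, and the highest of the other splits gave 0 and 0, so that 1 split reached the real value in each case. Each other split puts arrays of both days into each group, so the difference between the days enters the spread. Their 0 calls were thus to be foreseen and do not measure calls by chance.

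Markers of quiescent stellate cells, sinusoidal endothelial cells and hepatocytes fell together. Loss of non-stellate cells during culture may account for the endothelial and hepatocyte part. There 26 of 26 endothelial and 20 of 21 hepatocyte markers fell, 46 together, among them the abundant Alb (13.86 at day 0, 5.96 at day 7) and Stab2 (13.67 and 5.85). These counts are the pattern itself and were known when the bound was set, so they cannot decide for that loss. Lower marker RNA in cells that stayed would give them too and was not tested. Loss of non-stellate cells alone is argued against for the stellate part, where a rising stellate share would raise the markers. The 25 stellate markers held by no other list (4 more are shared) had a median of -4.83. Its 95% bootstrap interval (-5.94 to -2.19) resampled these genes, not arrays, so it does not measure the spread between samples. The fall of the whole list was known when the bound was set, so meeting that bound adds no independent support. Replacement by portal fibroblasts or mesothelial cells cannot be told apart from a change of state for the stellate part: a fall of over 10 of their 20 markers was first taken to exclude it, and 15 fell, but these include Dpt, which is also a stellate marker, while Fbln2 (4.21), Thy1 (2.63), Upk1b (1.16) and Wt1 (1.11) rose. A change of state of the stellate cells, which the design names, stays open as well, as does outgrowth of a subset, and neither was tested.

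Hhip and Ptch1 fell while Smo, Gli2 and Boc rose. A single faulty probe set is argued against for Hhip, as 4 of its 4 probe sets fell. For Ptch1 the question stays open, as 2 of its 3 probe sets fell, where the bound first written asked for all 3. A looser bound, which 2 probe sets meet, was written after the values were known and decides nothing. The 2 differ in size (-2.24 and -0.85) and the remaining one did not pass (0.05), so the size is open too. Hhip RNA of endothelial cells present at day 0 could account for the fall of Hhip and cannot be told apart from a change in stellate cells: its difference of -6.31 lies within the endothelial range of -8.80 to -1.11, but any strongly falling gene would. Lower pathway output in the stellate cells themselves stays open and was not tested. The rises of Smo, Gli2 and Boc cannot be told apart from a rising stellate share, which was not tested for them.

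Day 0 replicate 1 held neuronal transcripts, of which Nefl, a neurofilament chain, read 7.72 against 3.64 and 3.52 in the other day 0 arrays. A neuron list that left out such top genes lay 0.576 ± 0.123 (SE over 21 genes) log2 units higher there, above each of 1000 random lists matched on level, and an astrocyte list lay 0.381 higher (8 of 1000 random lists as high). RNA of brain or of peripheral nerve may be the source, although 9 oligodendrocyte markers had an excess of 0.0563 and 4 Schwann cell markers one of 0.0959 ± 0.0281 SE, both under the bounds set beforehand for excluding them (0.1 and the neuron excess divided by 2, 0.288). Those bounds do not decide, because they rest on the brightest probe set of each gene, and 3 of 8 probe sets of Mbp, which both cell types make, lay over 1 log2 unit above both other day 0 arrays (the highest at 9.78 against 5.77 and 5.70), and because Pmp22, at 11.33, would hide a small share and Cdh19, at 3.66, lay near the floor. Against both stand 0 of 17 probe sets of the other 8 oligodendrocyte markers and 0 of 6 of the Schwann cell markers with such an excess. Both explanations take the RNA to come from other tissue, and none within the stellate cells was tested.

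Among macrophage markers, lysozyme, Lyz2 (2.59), Cd14 (1.77) and Cd68 (1.06) rose, while Cd5l (-2.49) and Vsig4 (-1.66) fell, all chosen after their values were seen. The endothelial list varied more between day 7 arrays (SD of the array means 0.135) than between day 0 arrays (SD 0.0155).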
